A study of Homo sapiens with 16 samples.

How the data were processed

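RNA was measured in SW480 cells, an established colorectal cancer line, after transfection with 30 nM of small interfering RNA pools against SF3B1, against SRSF1 or with a non-targeting pool (siNT). Per the labels' protocols, total RNA was isolated with Trizol and a column kit, libraries were made with the TruSeq Stranded mRNA kit, and paired-end reads of 125 bases were sequenced on an Illumina HiSeq instrument. The main experiment had 12 libraries in 4 groups of 3: siNT and siSF3B1 at 48 h, and siNT and siSRSF1 at 72 h. A separate experiment had 1 siNT and 1 siSF3B1 library at 48 h, together with 1 Iso-Seq (long-read cDNA) library of each condition. The proteome measurements of the study were not analysed here.

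The deposited count tables held whole-number counts per gene for the 12 libraries and for the 2 libraries of the single experiment. Per the submitters' processing notes, the tools were Trimmomatic 3, STAR 2.4.2a, GSNAP and featureCounts of Subread 1.5.0-p2, and the genome build was hg19. Per the file headers, the counts of the 12 libraries came from featureCounts with paired fragments and a refGene annotation of 21 November 2014, and no strand option was set. The library kit marks strand, so fragments of a gene and of an antisense or overlapping gene cannot be told apart in these counts. The exons of 4904 of the 25963 genes overlapped exons of another gene, and values of such genes are uncertain. The counting options of the single experiment were not given in the sources used here.

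The authors deposited 4 lists of splice events as exon coordinates (unit other), 1 per knockdown in the triplicates and 2 for the single experiment, made with a reference annotation and with an Iso-Seq annotation. These lists gave the coordinates and type of each event but no score, p-value, direction or value per sample, and the caller and its threshold were not given in the sources used here. The authors also deposited Iso-Seq transcript models as exon coordinates (unit other), which hold no read numbers. The Iso-Seq models were assigned to siNT and siSF3B1 from the names they were deposited under, since the labels do not tie a sample to a model set. Coordinates are those of the deposited data on hg19, numbered from 1. The reference table given with the data was of GRCh38 and was used only for gene names and gene types. It matched 24753 of the 25963 symbols.

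Library totals ran from 16.1 to 24.0 M counts (M, 1e6) in the 12 libraries and were 13.2 and 13.7 M in the single experiment. The 10 genes with most counts held 4.17% to 5.85% of a library. Within groups, pairs of replicates differed by a chi-square of 3.09 to 25.3 per degree of freedom, so they were separate libraries and not resampled reads. Intervals given for shares are exact binomial (Clopper-Pearson) intervals at a confidence level of 95% and cover counting error only, and intervals of medians and rho are bootstrap intervals over genes.

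Groups were taken from the labels. Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the default expression filter, a group-means model over the 12 libraries and quasi-likelihood tests, with Benjamini-Hochberg adjustment over the 14180 genes tested and a threshold of 0.05. The 4 comparisons were siSF3B1 against siNT at 48 h, siSRSF1 against siNT at 72 h, siNT at 72 h against siNT at 48 h, and the difference between both knockdown effects. Levels are CPM, counts per 1e6 counts of a library, with TMM scaling, and log2 fold changes are those of the edgeR model. The tests, the groups, the 32 gene lists, the rule for naming genes and the alternatives were set before the data were examined, apart from the alternative and the tests said to have been chosen or added later. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it. The mitochondrial DNA list could not be tested, as 0 of its genes were in the count table.

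The labels speak of knockdowns done 3 times with paired siNT controls, and the numbers were therefore read as pairing libraries within a time point. The deviations of same-numbered libraries from their group means correlated with r of 0.24, 0.01 and 0.15 at 48 h and of 0.53, 0.48 and 0.33 at 72 h. Across both times r was 0.07, 0.02 and 0.16, and siNT at 72 h and 48 h were not treated as paired. The model without the pairs was the one set in advance, and the model with the replicate number as a block was an alternative.

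Named genes were both targeted genes and, per knockdown, the 10 highest and 10 lowest log2 fold changes among genes that passed the test, had a mean log2 CPM of at least 1 and separated all 3 knockdown libraries from all 3 controls, leaving out clone-type names and pseudogenes. For each list that was called or had at least 5 called members, up to 4 members with the smallest p were named. In the comparison of controls and in the difference between knockdowns, up to 5 genes per direction were named. Splice events were named for the 5 genes with most events per triplicate list and for 20 genes chosen in advance, while naming events by score could not be done, as the lists hold none. Other genes are named only where it is said that they were chosen after their values were seen.

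The single experiment was described with log2 ratios of CPM after adding a prior count of 2, and no test was made. The median of each list was placed among 10000 random lists of the same size matched on mean expression in 40 bins. Splice events were matched between lists by exact coordinates, and overlaps of genes were tested with Fisher's exact test, two-sided except for the genes shared by event lists, where it was one-sided for more sharing. Iso-Seq models were compared by junction chain. These steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

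The edgeR step was tested on negative binomial counts simulated from the mean levels and dispersions of the real genes over 14180 genes, of which 67, 67 and 66 were changed by 1.5, 2 and 4 fold. For siSF3B1 it recovered 68.7%, 89.6% and 98.5% of these, and 10 of 181 calls (5.5%) were false. For siSRSF1 it recovered 68.7%, 79.1% and 97.0%, with 15 of 178 calls (8.4%) false. For siNT at 72 h against 48 h it recovered 64.2%, 86.6% and 97.0%, with 7 of 172 calls (4.1%) false. For the difference between knockdowns it recovered 29.9%, 70.1% and 92.4%, with 7 of 135 calls (5.2%) false. With the block, the false share was 6.2% for siSF3B1, 7.9% for siSRSF1 and 3.8% for the difference. Camera gave an unadjusted p under 0.05 for 4 of 200 unchanged lists in siSF3B1 and 5 of 200 in siSRSF1, over 14180 genes. All simulated genes were drawn independently of each other and without an effect of the pairs. The false shares for lists of genes that vary together and for paired libraries were therefore not measured. Placing lists among random lists over 14180 genes put 4 of 100 unchanged lists below and 1 above the central 95%.

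The alternatives were RLE size factors, upper quartile scaling, no filter on low counts, a minimum of 10 counts, DESeq2 1.42.0, limma-voom, the replicate block, a test against a fold of 1.5, the 6 libraries of a comparison alone, and leaving out each library in turn. For lists they were the estimated correlation and fry. For single-exon genes they were a minimum of 100 mean counts and, chosen after seeing the data, only genes outside any other gene. For the single experiment they were a prior count of 0.5, a minimum of 10 counts and library totals without TMM. For splice events they were any shared base and a reciprocal overlap of at least 50%, and for Iso-Seq a tolerance of 10 bases, multi-exon models only and loci of both libraries.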

Results

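The data cover poly(A) RNA of SW480 cells in which SF3B1 or SRSF1, genes for splicing factors, had been lowered by RNA interference. SF3B1 encodes a subunit of the U2 snRNP that binds near the branch point, and SRSF1 encodes an SR protein that binds exons. The 3 siNT libraries at 48 h held 19.1, 16.1 and 19.3 M counts (M, 1e6), and the 3 siSF3B1 libraries at 48 h held 19.3, 24.0 and 18.8 M. The 3 siNT libraries at 72 h held 18.8, 20.9 and 18.2 M counts, and the 3 siSRSF1 libraries at 72 h held 19.9, 20 and 20.4 M. In the single experiment at 48 h, the siNT library held 13.2 M counts and the siSF3B1 library 13.7 M. Splice event lists and Iso-Seq transcript models came beside the counts.

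The targeted genes were examined first. SF3B1 (hg19 chromosome 2, 198256698 to 198299771) fell from 764 ± 30.6 CPM in siNT to 452 ± 20.6 CPM in siSF3B1 at 48 h (SD, n = 3). Its log2 fold change was -0.76 (SE 0.08, adjusted p = 0.00026, edgeR quasi-likelihood with Benjamini-Hochberg), and the knockdown libraries held 59.5%, 54.1% and 64.1% of the level of their paired controls. SF3B1 stood at 574 ± 41.4 CPM in siNT and 555 ± 45.9 CPM in siSRSF1 at 72 h (SD, n = 3). SRSF1 (hg19 chromosome 17, 56078280 to 56084707) stood at 513 ± 78.2 CPM in siNT and 328 ± 38.8 CPM in siSRSF1 at 72 h (SD, n = 3), or 61.5%, 66.0% and 64.8% of the paired controls. Its log2 fold change of -0.65 (SE 0.11) did not pass the edgeR test at an adjusted p of 0.057, and with the replicate block the adjusted p was 2.1e-05. At 48 h SRSF1 stood at 694 ± 67.8 CPM in siNT and 872 ± 60.9 CPM in siSF3B1, a log2 fold change of 0.33 with an edgeR adjusted p of 0.12, which was 0.0047 with the block. In the single experiment SF3B1 stood at 700 CPM in siNT and 170 CPM in siSF3B1, a log2 ratio of -2.04. All 3 siSF3B1 libraries lay below all 3 controls for SF3B1, and all 3 siSRSF1 libraries lay below all 3 controls for SRSF1, as their labels give.

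**Figure D1:**
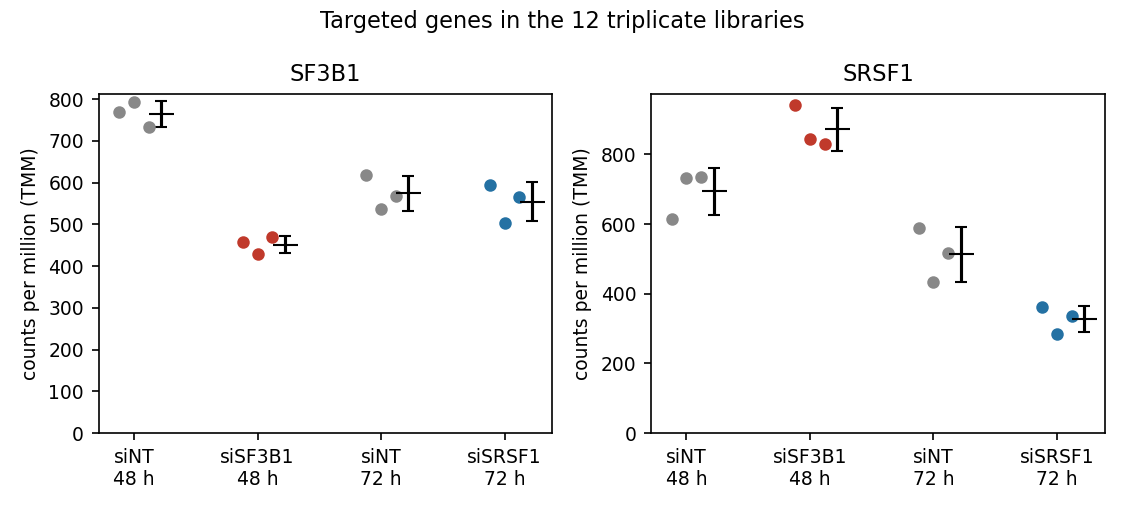
CPM (TMM) of SF3B1 and SRSF1 in each of the 12 triplicate libraries, by group; dots are libraries and the dash with bars is the mean ± SD (n = 3). Mean SF3B1 was 764 in siNT and 452 in siSF3B1 at 48 h, and mean SRSF1 was 513 in siNT and 328 in siSRSF1 at 72 h.

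The first comparison asked which transcripts differed when SF3B1 had been lowered for 48 h. CHAC1, which encodes a glutathione-degrading enzyme, rose from 4.83 ± 0.051 to 13 ± 1.5 CPM (SD, n = 3; log2 fold change 1.42). DDIT3, which encodes a transcription factor of the stress response, rose from 22.7 ± 3.1 to 51.9 ± 14 CPM, and GDF15, which encodes a secreted stress cytokine, rose from 7.02 ± 1.6 to 17.1 ± 6.4 CPM. DDX58, which encodes the RNA sensor RIG-I, rose from 8.85 ± 1.1 to 18.6 ± 3.3 CPM. MX2, an interferon-stimulated gene, fell from 8.86 ± 1.1 to 4.97 ± 0.16 CPM, and AASS, which encodes an enzyme of lysine breakdown, fell from 25.4 ± 5.8 to 14.3 ± 2.1 CPM. The adjusted p values (edgeR quasi-likelihood, Benjamini-Hochberg) were 6.1e-05 for CHAC1, 0.0083 for DDIT3, 0.015 for GDF15, 0.0013 for DDX58, 0.01 for MX2 and 0.012 for AASS. The other genes with the highest log2 fold changes were LSMEM1 at 1.37, DGCR11 at 1.19, PELI2 at 1.18, SLCO4A1-AS1 at 1.17, YY2 at 1.03 and PABPN1 at 1.01. SLCO4A1-AS1 and PABPN1 share exon bases with other genes, DGCR11 and YY2 lie inside another gene on the same strand, and the values of these 4 are uncertain. The other genes with the lowest were ZFPM2-AS1 at -0.99, SAMD9 at -0.86, TEX9 at -0.84, HPCAL4 at -0.81, AFF2 at -0.80, KSR2 at -0.66 and ENPP5 at -0.65. In all, 331 of 14180 genes passed the edgeR test, 231 higher and 100 lower. With the replicate block 2093 passed, 1161 higher and 932 lower. Without siSF3B1 replicate 2 the count was 30, without siSF3B1 replicate 1 it was 34, without siNT replicate 2 it was 46, without siNT replicate 1 it was 79 and without siNT replicate 3 it was 204.

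Among gene lists in siSF3B1, the genes of the ATF4 and amino acid response had the smallest camera p and the most called members, while the median of immediate early genes was larger (0.38, against 0.27). Of 37 tested members 10 were higher and 0 lower, 27 did not pass, and 17 were higher adjusted over the list alone (edgeR). SESN2, which encodes a leucine sensor, rose from 9.59 ± 1.2 to 18.8 ± 2.5 CPM (SD, n = 3; edgeR adjusted p = 0.0013). TRIB3, which encodes a pseudokinase, rose from 59.8 ± 2.2 to 116 ± 22 CPM, and SLC7A1, which encodes a transporter of cationic amino acids, rose from 409 ± 17 to 564 ± 36 CPM (edgeR adjusted p = 0.0052 for both). The camera adjusted p (Benjamini-Hochberg) of the list was 2.49e-14, with adjusted p = 0.117 with an estimated correlation. With the block 21 members were higher and 2 lower.

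The SR protein list in siSF3B1 had 3 of 23 members higher, 20 that did not pass, and 8 higher adjusted over the list alone. SRRM1 rose from 152 ± 4.8 to 214 ± 32 CPM, SON from 632 ± 19 to 852 ± 120 CPM and RSRP1 from 23.1 ± 3.7 to 41.4 ± 1.6 CPM (SD, n = 3; edgeR adjusted p = 0.015, 0.023 and 0.046), while SRRM2 did not pass (edgeR adjusted p = 0.081). The camera adjusted p of the SR proteins was 2.03e-06, with adjusted p = 0.493 with an estimated correlation. Immediate early genes, which respond early to growth signals, had 2 of 28 members higher and 9 higher adjusted over the list alone, with MYC from 328 ± 10 to 445 ± 36 CPM and IER2 from 30.9 ± 0.31 to 43.9 ± 3.3 CPM (edgeR adjusted p = 0.016 and 0.028), while JUNB and EGR1 did not pass. Their camera adjusted p was 1.37e-06, with adjusted p = 0.318 with an estimated correlation. The snoRNA host genes had 1 of 19 members higher and 2 higher adjusted over the list alone, and SNHG1 rose from 115 ± 8.5 to 220 ± 53 CPM (edgeR adjusted p = 0.027), while SNHG17, SNHG7 and EPB41L4A-AS1 did not pass. Their camera adjusted p was 0.0373, with adjusted p = 0.719 with an estimated correlation. The p53 target genes had 3 of 27 members higher, GDF15, SESN2 and BBC3, and 3 adjusted over the list alone. BBC3, which encodes the cell death protein PUMA, rose from 3.58 ± 0.56 to 6.66 ± 0.63 CPM (edgeR adjusted p = 0.017), and the camera adjusted p of the list was 0.0373, with adjusted p = 0.493 with an estimated correlation. BBC3 was also the 1 of 17 BCL2 family members that was higher, and adjusted over the list alone 3 were higher and 1 lower (camera adjusted p = 0.015, and adjusted p = 0.139 with an estimated correlation). Of 25 interferon-stimulated genes DDX58 was higher while MX2 and SAMD9 were lower, and adjusted over the list alone 1 was higher and 6 were lower. Their median log2 fold change was -0.18 (camera adjusted p = 0.0122, and adjusted p = 0.139 with an estimated correlation). With the block 13 SR proteins and 12 immediate early genes were higher and 0 lower, and of the snoRNA host genes 7 were higher and 1 lower. Of the genes above that did not pass, SRRM2, JUNB, EGR1, SNHG17, SNHG7 and EPB41L4A-AS1 then passed (edgeR adjusted p = 0.0028, 0.0094, 0.012, 3e-05, 0.016 and 0.0024). With the block 6 p53 targets were higher and 0 lower, 5 BCL2 family members higher and 1 lower, and 1 interferon-stimulated gene higher and 5 lower.

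Cytosolic ribosomal protein genes had 0 of 76 members past the edgeR test in siSF3B1 and 0 adjusted over the list alone, but 74 had a positive log2 fold change, with a median of 0.12. Their camera adjusted p was 1.24e-06, with adjusted p = 0.751 with an estimated correlation, and 21 members were higher with the block. RPL18, RPL17 and RPS15 were among the members with the smallest p without the block, and RPL17 shares exons with a readthrough gene. G2/M and mitosis genes had 0 of 45 members past the test and 0 adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.00493, and adjusted p = 0.79 with an estimated correlation). With the block 13 of them were lower and 3 higher, while PRC1, TOP2A, HMMR and KIF11 had the smallest p without the block. Of 24 genes of RNA polymerase II and elongation NELFA was higher (edgeR adjusted p = 0.036; 1 adjusted over the list alone; camera adjusted p = 0.0373, and adjusted p = 0.719 with an estimated correlation). Of 35 core snRNP genes PRPF3 was higher (edgeR adjusted p = 0.036; 1 adjusted over the list alone; camera adjusted p = 0.0453, and adjusted p = 0.79 with an estimated correlation). With the block 6 RNA polymerase II genes were higher and 0 lower, and 5 core snRNP genes higher and 1 lower.

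The U2 snRNP and SF3b list, which holds SF3B1, was not called in siSF3B1 (camera adjusted p = 0.587), with 0 of 21 members higher and 2 lower, and 3 higher and 2 lower adjusted over the list alone. The nonsense-mediated decay list was not called either (camera adjusted p = 0.188), with 2 of 18 members higher, and 4 higher and 2 lower adjusted over the list alone. With the block 4 members were higher and 2 lower in each of these 2 lists. Camera also called neither hnRNP proteins (0.107), splicing kinases (0.568), endoplasmic reticulum chaperones (0.427), heat shock genes (0.0587), S phase genes (0.134), histones (0.349) nor ribosome biogenesis (0.305), where the numbers are adjusted p values. Nor did it call cholesterol synthesis (0.587), WNT and stem cell genes (0.427), epithelial genes (0.5), mesenchymal genes (0.188), NF-kB genes (0.132), oxidative phosphorylation (0.962), glycolysis and hypoxia genes (0.348) or mTOR and MAPK genes with a known SRSF1 link (0.188). Single members of such lists did pass with the block. S phase genes then had 2 higher and 10 lower, and glycolysis and hypoxia genes 6 higher and 2 lower. Mesenchymal, heat shock and NF-kB genes had 6, 5 and 5 higher and 0 lower, while splicing kinases and histones had 0 called. The oxidative phosphorylation list had a positive median and mean and a camera direction below 0. Markers of other cell types had 0 members past the edgeR test, with camera adjusted p = 0.587 for fibroblast, 0.721 for blood cell and 0.427 for endothelial and neural markers. With the block 1 of 7 endothelial and neural markers was lower. The blood cell and the endothelial and neural lists had positive medians but negative means and test directions.

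**Figure D2:**
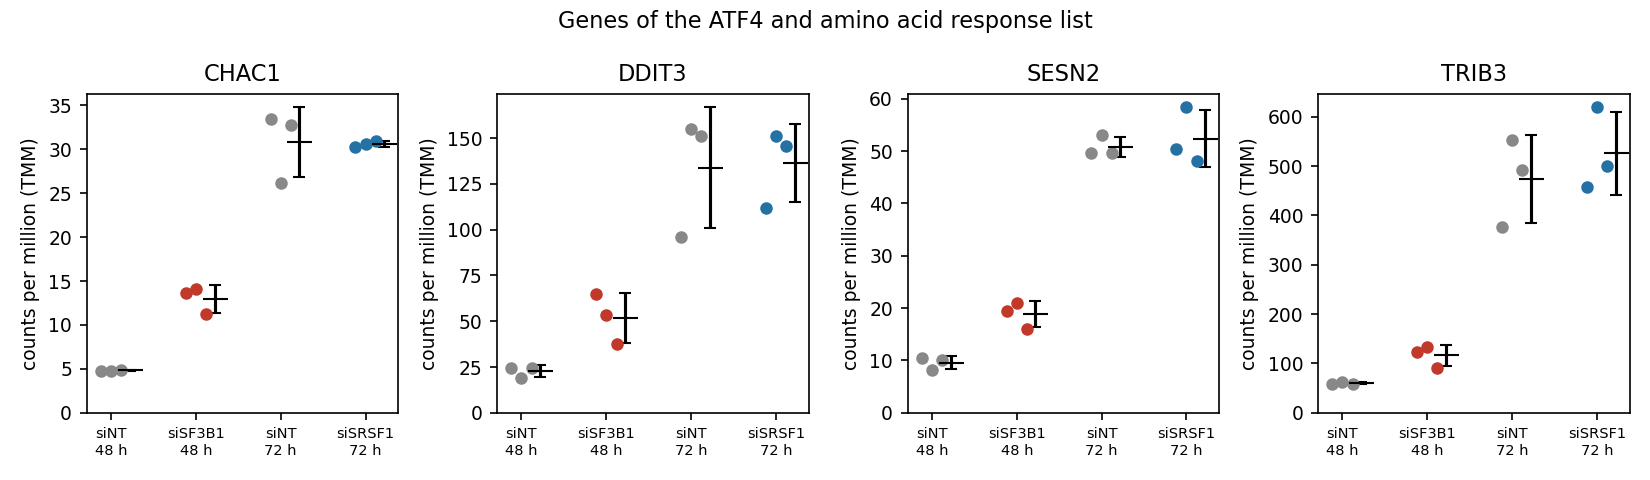
CPM (TMM) of CHAC1, DDIT3, SESN2 and TRIB3 in each of the 12 triplicate libraries, by group; dots are libraries and the dash with bars is the mean ± SD (n = 3). CHAC1 averaged 4.83 in siNT and 13 in siSF3B1 at 48 h.

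The second comparison asked which transcripts differed when SRSF1 had been lowered for 72 h. HIST1H2AC, a replication-dependent histone gene, rose from 8.08 ± 0.35 to 18.5 ± 1.8 CPM (SD, n = 3; log2 fold change 1.19). FAM120C rose from 10.5 ± 1.5 to 18.5 ± 0.76 CPM, and OSGEP, which encodes an enzyme of tRNA modification, rose from 15.4 ± 0.17 to 23.3 ± 1.6 CPM. The adjusted p values (edgeR quasi-likelihood, Benjamini-Hochberg) were 0.046 for HIST1H2AC, 0.041 for FAM120C and 0.046 for OSGEP. In all 6 genes passed, 6 higher and 0 lower, while 1033 had an unadjusted p under 0.05. The other 3 were FLJ23867, CDHR3 and FLJ43879, which lay outside the naming rule and were named after their values were seen. DESeq2 called 45 genes, 23 higher and 22 lower, and limma-voom called 3 higher. With the replicate block edgeR called 248, 108 higher and 140 lower. Without siNT replicate 2 the count was 26, without siSRSF1 replicate 3 it was 3, and it was 0 without siNT replicate 1, siNT replicate 3, siSRSF1 replicate 1 or siSRSF1 replicate 2.

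Replication-dependent histones, whose transcripts mostly lack a poly(A) tail, had 1 of 20 members higher in siSRSF1, and 6 higher adjusted over the list alone. All 20 had a positive log2 fold change, with a median of 0.81, while HIST1H2BD, HIST1H4H and HIST1H2AG did not pass on their own. Many members had low counts, as their median log2 CPM was 0.47, -0.33 and -0.26 in the siNT libraries at 72 h. The camera adjusted p (Benjamini-Hochberg) was 3.14e-15, with adjusted p = 0.383 with an estimated correlation, and 8 members were higher with the block. Without siSRSF1 replicate 1, but with its paired control kept, the median was 0.301, and within pairs the medians were 0.623, 0.886 and 0.754.

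Camera called 11 other lists in siSRSF1, of whose members beside SRSF1 the sterol reductase gene TM7SF2 had the smallest edgeR adjusted p, 0.32. S phase genes, G2/M genes, immediate early genes and ribosome biogenesis lay higher (camera adjusted p = 7.51e-05, 0.00133, 0.00173 and 0.00911), with adjusted p = 0.728 with an estimated correlation for each. Of 57 S phase genes 48 had a positive log2 fold change, with a median of 0.10 and CDT1, RFC5, CDC6 and RFC3 among them. Core snRNP genes, mTOR and MAPK genes and endoplasmic reticulum chaperones lay higher too (camera adjusted p = 0.0194, 0.0194 and 0.0373), with adjusted p = 0.728, 0.383 and 0.728 with an estimated correlation. The mTOR and MAPK list holds signalling genes with a known SRSF1 link and does not stand for these pathways as a whole. Ribosomal proteins, WNT and stem cell genes, cholesterol synthesis and SR proteins lay lower (camera adjusted p = 0.0315, 0.0315, 0.0373 and 0.0405), with adjusted p = 0.786, 0.728, 0.736 and 0.728 with an estimated correlation. The SR protein list holds the targeted SRSF1 and was not tested without it, so its call may rest on the target. Adjusted over the list alone, SRSF1 was the 1 member of these called lists beside histones that passed, and it was lower. With the block 1 S phase gene, 1 G2/M gene, 1 immediate early gene, 1 core snRNP gene and 1 mTOR and MAPK gene were higher, and 2 WNT and stem cell genes, 1 ribosomal protein gene and SRSF1 were lower. The ATF4 list was not called in siSRSF1 (camera adjusted p = 0.522), with 0 of 37 members past the edgeR test and 0 adjusted over the list alone. Markers of other cell types were not called in siSRSF1, with camera adjusted p = 0.264 for fibroblast, 0.504 for blood cell and 0.358 for endothelial and neural markers. With the block 1 of 5 blood cell markers was higher and 1 of 7 endothelial and neural markers lower in siSRSF1.

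The controls at both times were compared as the background of time and harvest. HSPA8, which encodes a chaperone, fell from 4320 ± 750 CPM in siNT at 48 h to 930 ± 220 CPM in siNT at 72 h (SD, n = 3), and RRM2, which encodes a subunit of ribonucleotide reductase, fell from 524 ± 24 to 143 ± 43 CPM. BEST1, which encodes an ion channel, rose from 0.608 ± 0.04 to 14.9 ± 5 CPM, and TRPV6, which encodes a calcium channel, rose from 2.57 ± 0.27 to 37.9 ± 24 CPM. LURAP1L, ABCG1 and LEMD1 rose by log2 fold changes of 3.79, 3.78 and 3.77, and FAM111B, HSPH1 and HMGCS1 had log2 fold changes of -2.04, -1.79 and -1.77. By edgeR 7043 of 14180 genes passed, 3738 higher and 3305 lower at 72 h. Upper quartile scaling moved the median log2 fold change of all genes to 0.10, from 0.034. The ATF4 list had 35 of 37 members higher (35 adjusted over the list alone; median 1.34; camera adjusted p = 1.12e-47, and adjusted p = 0.00214 with an estimated correlation). S phase genes had 56 of 57 members lower and G2/M genes 44 of 45, the same adjusted over the list alone (camera adjusted p = 1.51e-43 and 8.5e-27), with adjusted p = 0.0789 and 0.149 with an estimated correlation. Time, harvest and any batch of the libraries changed together in this comparison and cannot be told apart.

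The difference between both knockdown effects was tested directly, with target and time differing together. CHAC1 differed by 1.43 on the log2 scale (SE 0.17, edgeR adjusted p = 0.0015) and ITGA2, which encodes an integrin subunit, by -0.86 (SE 0.13, edgeR adjusted p = 0.016). SRSF1 differed by 0.98 and SF3B1 by -0.71 (edgeR adjusted p = 0.036 for both). By edgeR 5 genes passed, 3 higher and 2 lower, and the fifth, GUCA1B, lay below the expression minimum of the naming rule and was named after its values were seen. With the block 381 passed, 180 higher and 201 lower. Without siNT replicate 2 at 72 h the count was 16 and without siSF3B1 replicate 3 it was 10. It was 2 without siNT replicate 1 or 2 at 48 h, siSF3B1 replicate 2 or siNT replicate 3 at 72 h, and 3 without siNT replicate 3 at 48 h or siSRSF1 replicate 3. The ATF4 list differed with a camera adjusted p of 7.8e-11, with adjusted p = 0.233 with an estimated correlation. Histones differed with a median of -0.95 (camera adjusted p = 4.05e-09, and adjusted p = 0.478 with an estimated correlation), and SR proteins with a median of 0.26 (camera adjusted p = 4.32e-09, and adjusted p = 0.478 with an estimated correlation). The SR protein list was not tested without the targeted SRSF1 here either. With the block 14 members of the ATF4 list differed upward and 1 downward, 8 histones downward and 8 SR proteins upward, the targeted SRSF1 among them.

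Genes called in both knockdowns were counted next. No gene was shared, as 0 of the 231 higher and 0 of the 100 lower genes of siSF3B1 were called by edgeR in siSRSF1, where 6 genes were called higher and 0 lower and 1033 had an unadjusted p under 0.05. Independent lists would share 0.1 of the higher and 0 of the lower genes, so this count says nothing on sharing. With the block 22 genes were higher in both, among them DDX58, JUNB and NDRG1, where independent lists would share 8.84 (Fisher's exact test, p = 5.28e-05), and these 3 were named after their values were seen. With the block 55 were lower in both, among them APCDD1, TCF7 and KCNJ5, also named after their values were seen, where independent lists would share 9.2 (Fisher's exact test, p = 3.66e-29). Log2 fold changes correlated across genes with r = 0.171, and genes are not independent replicates. Of the 331 genes called in siSF3B1 222 (67.1%) had the same sign in siSRSF1, against 55.4% of the other genes. By direction the share was 71.4% of the 231 higher and 57% of the 100 lower genes. This difference was not tested, and the 55.4% was not split by direction. The overlap with the block ran the other way, with an odds ratio of 9.71 for lower and 2.9 for higher genes. The comparisons share no control library.

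In the single siSF3B1 experiment, with 1 library per condition and no replicate check, 324 of 330 genes called in the triplicates (98.2%) had the same sign, against 72.1% of the other genes. CHAC1 stood at 2.43 CPM in siNT and 17.5 CPM in siSF3B1, DDIT3 at 21.7 and 95.1 CPM, and SNHG1 at 123 and 363 CPM. Not every named gene repeated. ZFPM2-AS1, with 14 counts in each library, had a log2 ratio of 0.09, against -0.99 in the triplicates. PABPN1 (0.18, against 1.01) and ENPP5 (-0.28, against -0.65) kept their sign with smaller changes. Log2 ratios correlated with the triplicate log2 fold changes with r = 0.507 and rho = 0.558 across genes, which are not independent replicates. The median size of the log2 change of the called genes was 0.849, against 0.485 in the triplicates. The medians of the ATF4 list (0.603), SR proteins (0.556), snoRNA host genes (0.585) and immediate early genes (0.509) lay at percentile 100 of matched random lists. The p53 targets lay at percentile 99.97 with a median of 0.374, the BCL2 family at 99.64 and core snRNP genes at 98.89. G2/M genes (median -0.219) and S phase genes (median -0.176), the latter not called in the triplicates, lay at percentile 0. Also outside the central 95% and not called in the triplicates were heat shock genes (99.48), mesenchymal genes (99.19), NF-kB genes (98.8), glycolysis and hypoxia genes (98.32) and the U2 snRNP and SF3b list (97.54). The other 3 lists called in the triplicates lay inside the central 95% of matched random lists, with ribosomal proteins at percentile 91.07 (median 0.336), RNA polymerase II genes at 91.96 (0.268) and interferon-stimulated genes at 6.89 (-0.349).

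**Figure D3:**
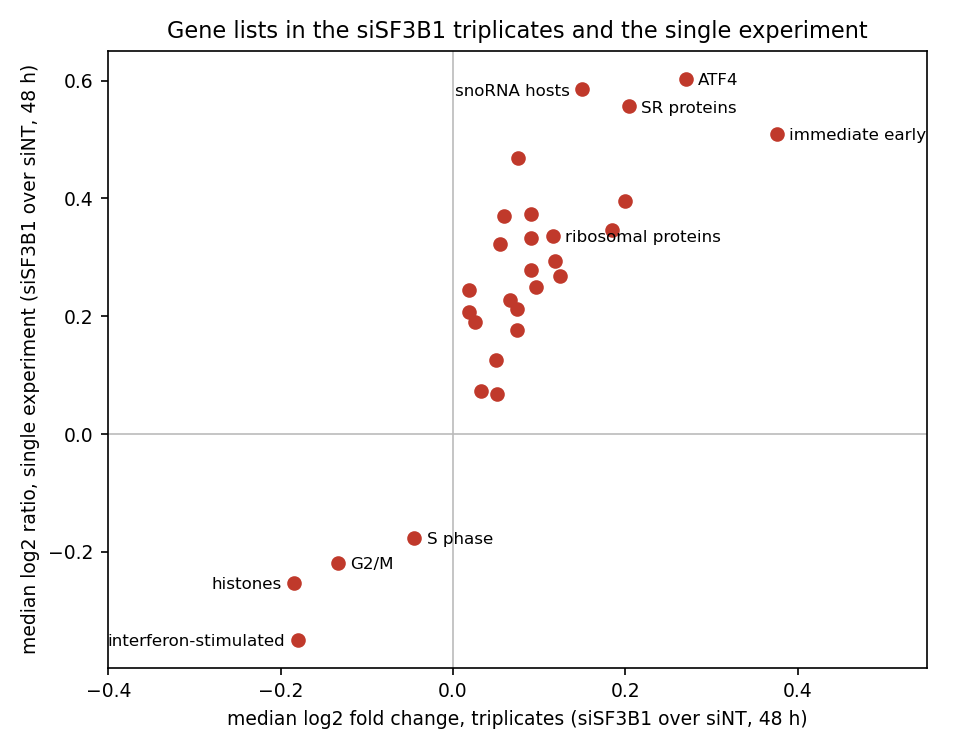
Median log2 fold change of single-exon genes and of each gene list with at least 10 tested members in the siSF3B1 triplicates (horizontal) and median log2 ratio in the single experiment (vertical); each dot is a list of genes. The ATF4 list lay at 0.27 and 0.603, and G2/M genes at -0.13 and -0.219.

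The number of exons is the property of a gene that a splicing factor knockdown names, and fold changes were set against it. In siSF3B1 the median log2 fold change was 0.051 for 607 genes with 1 exon block, 0.014 with 2 to 3, 0.041 with 4 to 7, -0.001 with 8 to 15 and -0.079 for 3339 genes with 16 or more, so the fall was not even. Of the latter 18 were higher and 57 lower, such as KSR2 and AASS, and among genes with 4 to 7 blocks 82 were higher and 9 lower. Among 13573 multi-exon genes the Spearman rho of fold change and block number was -0.177 in siSF3B1, 0.016 in siSRSF1, -0.174 for the difference between both knockdown effects and -0.175 in the single experiment, across genes, which are not independent replicates. Single-exon genes had 17 of 607 members higher and 1 lower in siSF3B1, and their median lay 0.058 above that of multi-exon genes (camera p = 0.02, and p = 0.0838 with an estimated correlation). The 186 single-exon genes inside another gene on the same strand had a median of 0.223, the 50 on the opposite strand 0.051 and the 371 outside any other gene -0.002. In siSRSF1 the difference was 0.017 and not called by camera, while among genes with at least 100 mean counts it was 0.037 and called at the preset correlation but not at an estimated one. Histone genes with 1 exon block were not left out, so this call may not be independent of the higher histones in siSRSF1.

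**Figure D4:**
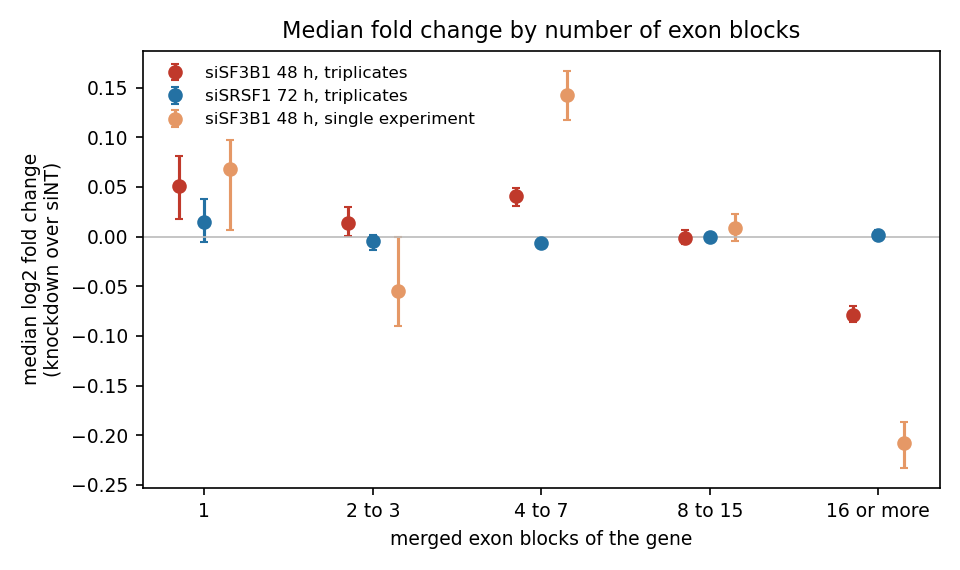
Median log2 fold change over siNT by the number of merged exon blocks of a gene, for the siSF3B1 and siSRSF1 triplicates and the single siSF3B1 experiment; bars are 95% bootstrap intervals over genes. Genes with 16 or more blocks lay at -0.079 in the siSF3B1 triplicates, -0.208 in the single experiment and 0.002 in siSRSF1.

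The authors' deposited lists of splice events gave 4851 events in 2725 genes for the siSF3B1 triplicates and 556 events in 446 genes for the siSRSF1 triplicates. KIAA1191 held 23 events, the snoRNA hosts GAS5 and SNHG1 held 21 and 18, CAST 17 and PTGES3 16 in the authors' deposited siSF3B1 list. IRF3 held 8, TMX2 7, THTPA 6, WNK1 5 and LRRC75A-AS1 4 in the authors' deposited siSRSF1 list. Skipped exons made up 82.0% of the deposited siSF3B1 events (exact 95% interval 80.9 to 83.1) and 75.7% of the siSRSF1 events (71.9 to 79.2). Mutually exclusive exons made up 14.1% and 6.8%, alternative 3' sites 1.6% and 7.2%, alternative 5' sites 1.1% and 6.5%, and retained introns 1.2% and 3.8% of the deposited events. Each of these 5 shares differed between both deposited lists (Fisher's exact test, adjusted p = 0.000547, 5.76e-07, 8.76e-12, 1.71e-13 and 2.44e-05), where events of 1 gene are not independent. The skipped exons in the deposited lists had a median length of 93 bases in siSF3B1 and 115 in siSRSF1, against 124 for internal exon blocks of the tested genes. A length that is a multiple of 3 was held by 47.7% of them in siSF3B1 and 54.6% in siSRSF1, against 39.4% of internal blocks. The blocks were merged from overlapping exons of a gene, so their lengths are not those of single exons and the measures are unlike.

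Named exons recurred between the deposited lists. An exon of OSBPL3, which encodes a lipid-binding protein (hg19 chromosome 7, 24902819 to 24902911, 93 bases), and one of the proliferation marker MKI67 (chromosome 10, 129913192 to 129914271, 1080 bases) were in all 4 of the authors' deposited lists. An exon of the kinase gene RPS6KB1 (chromosome 17, 57991996 to 57992064, 69 bases) was in all 3 deposited siSF3B1 lists. Exons of RAC1 (chromosome 7, 6438293 to 6438349, 57 bases) and SYK (chromosome 9, 93629413 to 93629481, 69 bases) were in the deposited siSRSF1 list and in both lists of the single siSF3B1 experiment. A retained intron of SRSF1 (chromosome 17, 56081363 to 56082283) was in both triplicate lists of the authors' deposited data, and an alternative 3' site of MKNK2 was in the siSRSF1 list alone. MCL1, CLK4, SRSF3 and CDC25C were in none of the 4 deposited lists. The deposited lists give no direction, so none is stated here. Of the deposited siSF3B1 triplicate events 2142 (44.2%, 42.8 to 45.6) were also in the single experiment with the reference annotation and 1226 (25.3%, 24.1 to 26.5) in that with the Iso-Seq annotation, by exact coordinates. By any shared base these were 2391 (49.3%) and 2378 (49.0%) of the deposited events, so both annotations differed little by that measure. All 3 deposited siSF3B1 lists shared 1088 events, 1032 of them skipped exons, and all 4 lists shared 28. The deposited siSF3B1 and siSRSF1 lists shared 80 events and 198 tested genes. Within the low, middle and high tertile of expression the deposited lists shared 12, 47 and 139 genes, where independent lists would share 3.4, 20.9 and 82.6 (Fisher's exact test, one-sided, adjusted p = 0.000111, 1.47e-08 and 2e-14), with odds ratios of 4.17, 3.16 and 2.9. The number of exons of a gene was not matched, so this sharing need not mean common targets.

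Genes with deposited events were compared with the counts. Among snoRNA host genes 11 of 19 held an event in the authors' deposited siSF3B1 list, where matched random lists held 4.8 (permutation test for an excess, adjusted p = 0.028), GAS5 and SNHG1 among them. None of the other lists passed this test for the deposited siSF3B1 events. The test did not ask for fewer events, and cytosolic ribosomal proteins held an event of the authors' deposited siSF3B1 list in 13 of 76 members, where matched random lists held 29.9 (22 to 38). Of 6 tests of whether genes with a deposited siSF3B1 event were called higher or lower by edgeR more or less often than other genes of like expression, 0 passed (Fisher's exact test, smallest adjusted p = 0.128), which does not show that they did not differ. In the middle tertile of expression 1 gene with a deposited event was called lower, where 5.9 would be expected, and over all genes 55 were called higher, where 44.3 would be expected, the latter without matching. The median log2 fold change of genes with a deposited siSF3B1 event lay above that of other genes by 0.066 (95% bootstrap interval 0.007 to 0.115) in the low tertile of expression and 0.034 (0.014 to 0.047) in the middle one, and by 0.003 (-0.008 to 0.015) in the high one. For the deposited siSRSF1 events these differences were -0.09 (-0.123 to -0.023), -0.01 (-0.027 to 0.018) and -0.004 (-0.021 to 0.011).

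The Iso-Seq models, from 1 library per condition and so without a replicate check, numbered 34951 in 11029 loci for siNT and 37677 in 11269 loci for siSF3B1. SF3B1 itself had 16 models in siNT and 8 in siSF3B1. Models averaged 9.36 exons in siNT and 8.17 in siSF3B1, with a median length of 2574 and 2118 bases. Single-exon models made up 12.6% (exact 95% interval 12.3 to 13) in siNT and 16.2% (15.8 to 16.6) in siSF3B1. Of 66761 introns spliced in both libraries 2.17% were retained in a siNT model and 2.69% in a siSF3B1 model, and 1336 were retained in siSF3B1 alone against 989 in siNT alone. Both libraries shared 7707 junction chains, 25.2% of those in siNT.

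The junctions of the authors' deposited siSF3B1 skipped exons were looked up in the Iso-Seq models. Of 3405 distinct skipping junctions 1066 were in the siSF3B1 library alone and 137 in the siNT library alone, a share of 88.6% (86.7 to 90.4), against 44.2% of all junctions seen in 1 library, while 428 were in both and 1774 in neither. A closer baseline is given by internal exons of both libraries that a junction skipped in 1 library only. Of these exons 53.3% (52.5 to 54.2) were skipped in siSF3B1. Of 3977 distinct pairs of inclusion junctions of the same deposited events 375 were in siSF3B1 alone and 383 in siNT alone, a share of 49.5% (45.9 to 53.1). For the distinct skipping junctions of events in all 3 deposited siSF3B1 lists the share was 93.5%, but 1 of these lists was made with the Iso-Seq annotation, so these junctions were partly chosen through the models in which they are counted. For those of the deposited siSRSF1 events it was 60.3% (48.5 to 71.2), an interval that holds the 53.3% of skipped internal exons.

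**Figure D5:**
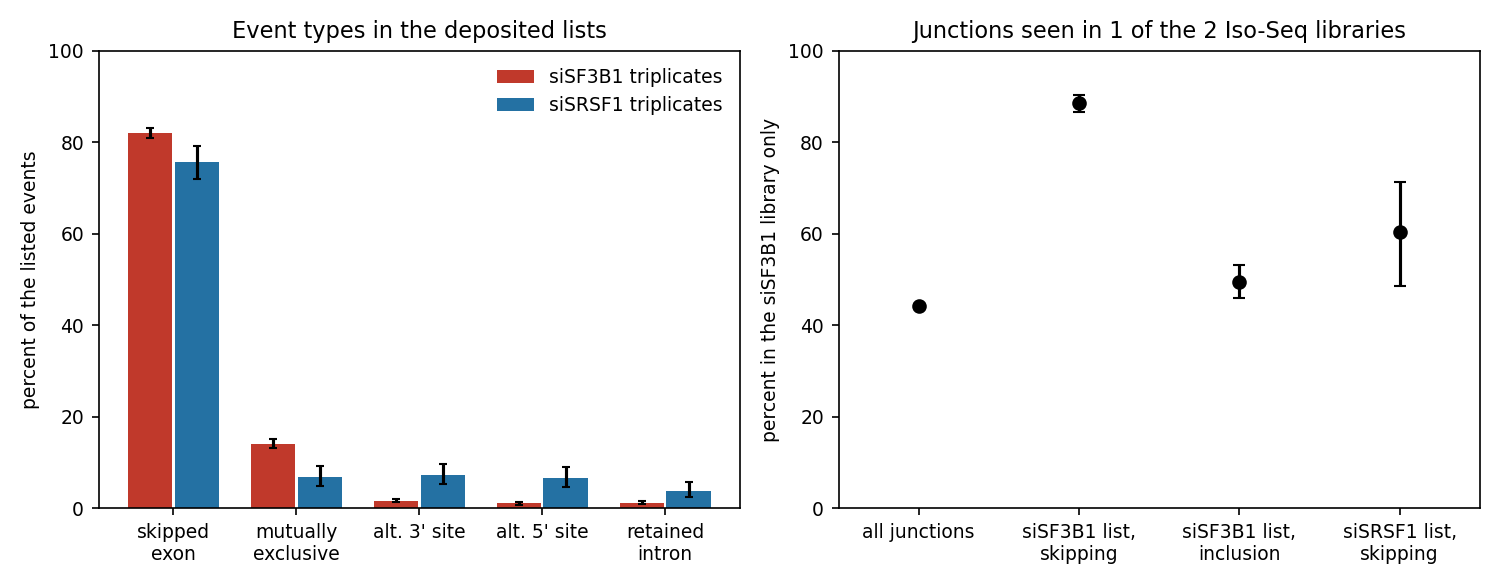
Left, percent of events of each type in the authors' deposited siSF3B1 and siSRSF1 triplicate lists; right, percent in the siSF3B1 library among junctions seen in 1 of the 2 Iso-Seq libraries; bars on both are exact 95% intervals. Skipping junctions of the siSF3B1 list lay at 88.6% and inclusion junctions at 49.5%.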

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

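The test on S phase genes and the histone medians within pairs and with a pair left out were chosen only after the result was seen, as was the restriction to single-exon genes outside any other gene as an alternative. The pattern with exon number was widened from single-exon genes after the trend had been seen, and the tests of transcript length and of short Iso-Seq models were added after related values had been seen, though before their own values were. The splits with the replicate block were likewise added after the counts with the block had been seen.

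A difference between both knockdown effects marked 5 genes, by the direct test of that difference with edgeR. CHAC1 differed by 1.43 on the log2 scale, at 1.42 in siSF3B1 and -0.01 in siSRSF1, and GUCA1B by 3.21. SRSF1 differed by 0.98, ITGA2 by -0.86 and SF3B1 by -0.71. SF3B1 and SRSF1 were each targeted in 1 arm only. Target and time differ together, so the test does not part them. Of 100 splits drawn at random, the real one among them, 7 gave at least as many genes as the 5 of the real grouping, with 212 in the highest other. These splits ignore the pairs. Of the 6 others, 5 kept the real groups at 48 h and so hold the effect of siSF3B1, and the sixth gave 53 genes, so this count does not settle whether chance is excluded. With the block, which called 381 genes, 2 of the 32 splits that swap labels within pairs gave as many, with 1565 in the highest other. That one exchanges siSRSF1 and siNT in all pairs and adds the 2 effects, so it settles nothing on chance either. The next highest, 240, also kept the real groups at 48 h. No group had over 3 samples, so single samples were not tested.

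In siSF3B1, 1 of 10 splits of the 6 libraries, the real one, gave 331 genes, with 0 in the highest other. In siSRSF1, 2 of 10 splits gave at least the 6 genes of the real grouping, with 64 in the highest other. That other split set siNT replicates 1 and 3 and siSRSF1 replicate 1 against the rest and parts 1 pair, which points to a structure of the samples, while the other 3 splits that part all pairs, as the real one does, gave 0. For siNT at 72 h against 48 h, 1 of 10 splits gave 7043 genes, with 0 in the highest other. With 10 splits, the splits are too few for a share under 0.05. With the block, 1 of 4 splits within pairs gave 2093 genes in siSF3B1 and 1 of 4 gave 248 in siSRSF1, with 0 in the highest other of each, and 4 splits are too few as well.

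The log2 fold change fell with the number of exon blocks in siSF3B1. Low counts of single-exon genes are argued against, as these lay 0.09 above multi-exon genes of like expression (95% bootstrap interval 0.044 to 0.134), and transcript length is argued against as the whole cause, as the partial rho with length and expression held was -0.156. Host gene fragments may account for part of the single-exon end, since single-exon genes outside any other gene lay only 0.006 from all multi-exon genes (-0.03 to 0.036). This value was not matched on expression, unlike the 0.09. The median mean log2 CPM was 0.83 for single-exon genes and 3.03 to 5.59 for the classes with more blocks. The 0.006 therefore does not show that genes outside any other gene equal multi-exon genes of like expression. A lower yield of transcripts with many introns may account for the rest, with a rho of -0.177 among multi-exon genes, but this value nearly restates the pattern and does not by itself part that explanation from others. Retained introns were not measured per gene in these counts.

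Replication-dependent histones were called higher in siSRSF1 by camera at the preset correlation, but not at an estimated one. Whether those libraries held more RNA without a poly(A) tail was not decided. The median of 108 other such RNAs was -0.091 (-0.163 to -0.014), which goes against a general rise. But at 48 h these other RNAs summed to 156, 149 and 147 CPM in siNT and 228, 185 and 170 CPM in siSF3B1. Histones there summed to 245, 156 and 163 CPM in siNT and 226, 164 and 155 CPM in siSF3B1. Both sets moved apart, so the other RNAs need not track histones. Without the pairs, 1 library may decide the size of the difference, as the median was 0.301 without siSRSF1 replicate 1, against 0.81 with all and 1.166 at the highest, but that fit kept the paired control, which had the highest histone level of the controls at 72 h. The medians within pairs were 0.623, 0.886 and 0.754, and with the block they were 0.77 (0.568 to 1.061) without pair 1, 0.933 (0.381 to 1.002) without pair 2 and 0.729 (0.396 to 1.12) without pair 3, so replicate 1 alone did not carry the paired difference, while the intervals are too wide to decide on the other pairs. More cells in S phase may contribute and were not decided on, as the bound of 0.1 was set after the S phase median of 0.10 (0.083 to 0.115) had been seen, and an effect of SRSF1 itself was not tested. Between the controls S phase genes had a median of -1.05 and histones of -0.43, so both did not move by like amounts there or in siSRSF1.

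The siSF3B1 Iso-Seq library held a larger share of single-exon models. A larger share of short models is argued against, as weighting siSF3B1 to the lengths of siNT widened the difference. The siSF3B1 share was 16.2% unweighted and 19.7% weighted, against 12.6% in siNT. The weighted difference was 7.08 percentage points (5.28 to 8.92). Genomic DNA as the whole cause is argued against too, as the share of single-exon models on the sense strand of a gene was higher by 3.34 points (1.77 to 4.92). Antisense models and those outside genes made up 2.8% of all models in siNT and 3.06% in siSF3B1, beside 9.81% and 13.15% for sense ones, so a small part from genomic DNA stays open. Retention of introns may contribute, with 57.5% (55.4 to 59.5) of introns retained in 1 library being so in siSF3B1, where 51.9% of models came from it. Shorter cDNA in the siSF3B1 library stays open, with a median model length of 2118 bases against 2574 in siNT. Weighting by length does not exclude it, as a cut transcript can have 1 exon at any length. The length ratio of 0.999 over shared junction chains decides nothing either, as the chain fixes all but the ends. With 1 library per condition, the condition and the library cannot be told apart.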

How the results depend on the processing

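Restricting single-exon genes to those outside any other gene was the one alternative chosen only after the result was seen. The cause was not tested for any change below, unless stated.

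The count of genes called in siSF3B1 (331) was 572 without the filter, 822 with DESeq2, 2093 with the replicate block, 9 against a fold of 1.5, 523 with 6 libraries, and 30 to 266 with 1 library left out. That in siSRSF1 (6) was 34 without the filter, 45 with DESeq2, 3 with limma-voom, 248 with the replicate block, 0 against a fold of 1.5 (55 at an unadjusted p under 0.05), 1 with 6 libraries, and 0 to 26 with 1 library left out. That between controls (7043) was 1284 against a fold of 1.5 and 6059 to 7068 with 1 library left out. That of the difference between knockdowns (5) was 40 without the filter, 98 with DESeq2, 381 with the replicate block, 1 against a fold of 1.5 and 2 to 16 with 1 library left out. Scaling by RLE and a minimum of 10 counts left each of the 4 counts within 1.5 times. By DESeq2 59.7% of siSF3B1 calls were higher, against 69.8%. Between controls upper quartile scaling gave 61.9% higher, against 53.1%. A fold minimum asks for larger changes by its construction.

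Called lists numbered 11 in siSF3B1, 12 in siSRSF1, 21 between controls and 10 in the difference. With an estimated correlation these were 0, 0, 1 and 0, and with fry 4 in siSF3B1, 1 in siSRSF1 and 0 in the difference. With 1 library left out they were 8 to 13, 6 to 11, 19 to 22 and 8 to 12.

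SF3B1 (-0.76) was not called against a fold of 1.5 (-0.76), and ranged from -0.79 to -0.72 with 1 library left out. SRSF1 (-0.65, adjusted p = 0.057) was called by edgeR with upper quartile scaling (-0.65), without the filter (-0.64) and with the replicate block (-0.64), and by DESeq2 (-0.64). With 1 library left out it ranged from -0.74, called without siNT replicate 2 (edgeR adjusted p = 0.0086), to -0.52, and its edgeR adjusted p was 0.5 with the 6 libraries alone and 1 against a fold of 1.5. HMGCS1 in siSRSF1, not called at -0.23, ranged from -0.47 to 0.09 with 1 library left out, and was 0.09 without siNT replicate 1 (edgeR adjusted p = 0.89). Of 31 named genes called in siSF3B1, 246 of 279 values under alternatives with all libraries kept the call, and 74 of 186 with 1 library left out. For siSRSF1 these were 19 of 27 and 3 of 18, between controls 70 of 70 and 60 of 60, and for the difference 28 of 32 and 28 of 48. None turned sign.

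The replicate block gave 22 genes higher and 55 lower in both knockdowns, against 0 and 0. It left the call of single-exon genes as it was. No paired analysis was possible because the pairs lie within a time point for siNT at 72 h against 48 h.

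Single-exon genes in siSF3B1 (0.058) lay 0.028 higher with at least 100 mean counts and 0.006 higher when outside any other gene, not called by camera in either. In siSRSF1 (0.017, not called) they lay 0.037 and 0.046 higher and were called in both at the preset correlation, in neither at an estimated one. Histone genes were not left out of these calls. Between controls, uncalled, their sign turned to 0.031 and 0.052, and in the difference to -0.004 and -0.017. Deposited siSF3B1 events shared with the Iso-Seq list (1226) numbered 2378 by any base and 2361 by a reciprocal 50%, while those shared with the reference list (2142) numbered 2391 and 2387. Same-sign genes of the single experiment were 95.8% with library totals without TMM, against 98.2%. Chains of siNT in both Iso-Seq libraries were 26.7% within 10 bases, and mean exons differed by -1.02 in multi-exon models, against -1.19. The alternative of keeping the events with the highest scores was not run, as the deposited lists hold no score. With 3 libraries per group and 16.1 to 24.0 M counts, changes of 1.5 fold were recovered in 68.7% of simulated siSF3B1 genes.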

Other observations

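Between the controls, further gene lists changed from 48 h to 72 h. Heat shock genes had 14 of 17 members lower and 1 higher (camera adjusted p = 1.31e-14, and adjusted p = 0.118 with an estimated correlation), with HSPH1 from 816 ± 110 to 236 ± 53 CPM (SD, n = 3; edgeR adjusted p = 1.6e-07). Cholesterol synthesis genes had 20 of 25 members lower and 1 higher (camera adjusted p = 3.2e-08, and adjusted p = 0.237 with an estimated correlation), with HMGCS1 from 147 ± 20 to 43.3 ± 15 CPM (edgeR adjusted p = 2.5e-06). Immediate early genes had 20 of 28 members higher and 0 lower (camera adjusted p = 5.22e-10, and adjusted p = 0.118 with an estimated correlation). The hnRNP proteins had 22 of 28 members lower and the U2 snRNP and SF3b list 16 of 21 (camera adjusted p = 1.31e-09 and 2.68e-06), with adjusted p = 0.149 and 0.182 with an estimated correlation. CHAC1, DDIT3, SESN2 and TRIB3 stood higher in the controls at 72 h than in the siSF3B1 libraries at 48 h, and the arms compared in the difference between knockdowns began from different levels.

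Summed over 20 replication-dependent histone genes, the siNT libraries at 72 h held 176, 83.3 and 102 CPM and the siSRSF1 libraries 309, 165 and 167 CPM. The siNT libraries at 48 h held 245, 156 and 163 CPM and the siSF3B1 libraries 226, 164 and 155 CPM. With the replicate block, HIST1H2BK rose from 43.8 to 92.4 CPM in siSRSF1 (edgeR adjusted p = 1.5e-07), CUX2 fell from 10.4 to 4.44 CPM (edgeR adjusted p = 0.00014) and DKK3 fell from 14.3 to 7.75 CPM (edgeR adjusted p = 0.00013). These 3 genes were chosen after their values were seen and did not pass without the block. In the single experiment, single-exon genes inside another gene on the same strand had a median log2 ratio of 0.537, those on the opposite strand 0.051 and those outside any other gene -0.068.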
